A study of Homo sapiens with 3 samples.

How the data were processed

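H3K9ac chromatin immunoprecipitation libraries came from HEK293T cells 24 h after calcium phosphate transfection, 1 library each for FLAG empty vector, HDAC1-FS and HDAC1. Cells were fixed with formaldehyde and chromatin was sonicated, per the labels' protocols. Groups were taken from the treatment labels. The 4 lists used hold genomic regions for condition 1 and condition 2 of the HDAC1-FS and HDAC1 comparisons, each against empty vector. Per the file headers, the regions are those unique to 1 condition, and the authors gave each region a score. The lowest scores lie just above 3, and the form of the lists matches the differential regions that MACS2 writes. The unit of the score, the scaling between libraries, the filtering of duplicate and multiply aligned reads and the use of an input library are not given in the sources used here. The submitters' processing notes name Bowtie2 2.3.5.1, deepTools 3.5.1, MACS2 2.2.7.1 and the build hg38, without their roles or order. A different scaling of libraries would move regions between the conditions, so the split between conditions rests on that choice. The score was used to describe, rank and filter the regions of each list, with the same minimum scores for all lists. Scores of different lists that stand side by side are each list's own values and are not read as differences.

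The authors' regions were used as deposited. Genes and coordinates came from the RefSeq table of GRCh38.p14, whose main chromosomes are those of hg38, and all coordinates are counted from 1. The lists held 18 condition 2 regions of the HDAC1-FS comparison and 4 of the HDAC1 comparison on other contigs, which entered counts but no analysis of genes or distance. The table has no strand, exons or sequence, which changed the planned design in several ways. In place of promoters, windows of 1 kb on each side of both annotated ends of 19974 protein-coding genes were used and called gene ends, so a transcription start and a transcript end are not told apart. Random lists were matched on quintile of gene length and on crowding of gene ends in place of promoter CpG content. Random placements stayed on the same chromosome, in stretches with annotated genes, and stretches of over 2 Mb without a gene were left out. The planned rule for naming the HDAC1 library, which needed exons, was not applied, so the names condition 1 and condition 2 were kept.

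Regions overlapped if they shared at least 1 bp. Overlap and location were set beside 100 random placements. These were not limited to sites with H3K9ac, where regions can be called, so they describe location and overlap and test neither. The share of each gene list with a region at a gene end was set beside 10000 random gene lists, with percentiles counting ties as partly below. Of 925 list members, 922 were matched to the table. Shares have exact Clopper-Pearson 95% intervals, and an upper limit for a share of 0 is 3 counts of the total. No p-values were computed across regions or genes, since each group had 1 library. Read depth is unknown, so its effect on the number of regions could not be examined. Leaving out replicates, splits of the samples and paired fits do not apply to 1 library per group.

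Named genes were chosen before the data were examined by a fixed rule. Per list of regions, it takes the 10 protein-coding genes with the highest-scoring regions at gene ends, up to 4 members of each gene list with the highest-scoring regions, HDAC1, and the 5 genes with regions of the same condition in both comparisons and the highest score in the HDAC1 comparison. Genes and regions outside it are said to have been chosen after their values were seen. The gene lists cover the HDAC family and its complexes, acetyltransferases and bromodomain proteins, cell cycle, DNA replication, CDK inhibitors and p53 targets, apoptosis, migration, immediate early genes, heat shock and unfolded protein response, interferon, ribosomal proteins, oxidative phosphorylation, proteasome, splicing, cholesterol synthesis, glycolysis, replication-dependent histones, HOX, REST targets and kidney. Haematopoietic, liver, skeletal muscle, epidermal and olfactory receptor lists stand for other cell types.

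Alternatives were scores of at least 5 and at least 10, merging of regions within 1 kb, main chromosomes alone, windows of 500 bp and 2.5 kb, an overlap of 50% of both regions, overlap of genes, and unmatched random lists. Further alternatives were chosen after seeing the data: regions of at least 400 bp, removal of regions at HDAC1 and of high-scoring regions at pseudogenes, HDAC1-comparison regions with a score of at least 5 against all regions of the HDAC1-FS comparison, and a background of genes with a region in the HDAC1-FS comparison. The random placements and matching described above were also set after the reference was seen. Condition 1 regions were compared with draws at the same distances from gene ends that carry condition 2 regions, 100 draws with random direction and 100 that kept the direction into or out of the gene. The direction-keeping draws, and a count of regions with neighbours on both sides among those with any neighbour, were added after the result with random direction had been seen. The draws lie only at genes that carry condition 2 regions, while condition 1 regions can lie at any gene.

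Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Tested on simulated regions, the overlap search found 500 of 500 planted overlaps and the gene assignment 300 of 300 planted genes, over 19974 genes. A planted list reached the percentile 100, and 6 of 200 random lists reached the 97.5th percentile. Hits in these list checks lay at genes drawn at random, so they check the calculation and not how lists of related genes behave.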

Results

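H3K9ac, an acetyl mark on histone H3 found at active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in HEK293T cells, a human embryonic kidney cell line. Cells received a FLAG empty vector, an HDAC1 plasmid or an HDAC1-FS plasmid for 24 h. HDAC1 is a histone deacetylase, and the series concerns proteins made by ribosomal frameshifting at codon repeats. Each of the 3 groups had 1 library, so no difference given here has a replicate check. The empty vector served as comparator for both HDAC1-FS and HDAC1, and each comparison was given as a list of regions for condition 1 and a list for condition 2. The labels do not say which condition number was which library, so the condition numbers are kept and no direction of change is drawn. Sequencing depth is unknown, because the lists hold no read counts. Exact binomial 95% intervals cover counting error only.

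The HDAC1-FS comparison asked where H3K9ac differed between cells with HDAC1-FS and cells with empty vector. Condition 2 regions lay at the ends of 10809 of 19974 protein-coding genes (54.1%, 95% interval 53.4 to 54.8%), and condition 1 regions at 34. At the authors' threshold, condition 2 regions lay at 42 of 42 splicing factor genes, 75 of 78 ribosomal protein genes, 30 of 31 proteasome genes and 25 of 25 genes of acetyltransferases and bromodomain proteins. Of the lists for other tissues, condition 2 regions lay at 0 of 44 olfactory receptors, 1 of 31 liver genes, 1 of 27 epidermal genes, 4 of 37 haematopoietic genes and 6 of 28 skeletal muscle genes. Regions can be called only at sites with H3K9ac, and the lists do not say which genes carried the mark. The contrast between these gene lists may therefore follow from which genes were active. The highest-scoring condition 1 region at a gene end lay at TUBGCP5, a subunit of the gamma-tubulin complex, with an authors' score of 20.7.

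In all, 20841 regions were listed for condition 2 and 164 for condition 1, so condition 2 held 99.2% of the regions (95% interval 99.1 to 99.3%). The condition 2 regions covered 9.62 Mb with a median width of 379 bp, and the condition 1 regions covered 46.2 kb with a median width of 256.5 bp. Median scores were 4.57 (quartiles 4.03 to 5.20) for condition 2 and 4.80 (4.24 to 6.42) for condition 1. The share was opposite among regions with a score of at least 10, of which 11 belonged to condition 1 and 1 to condition 2.

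**Figure D1:**
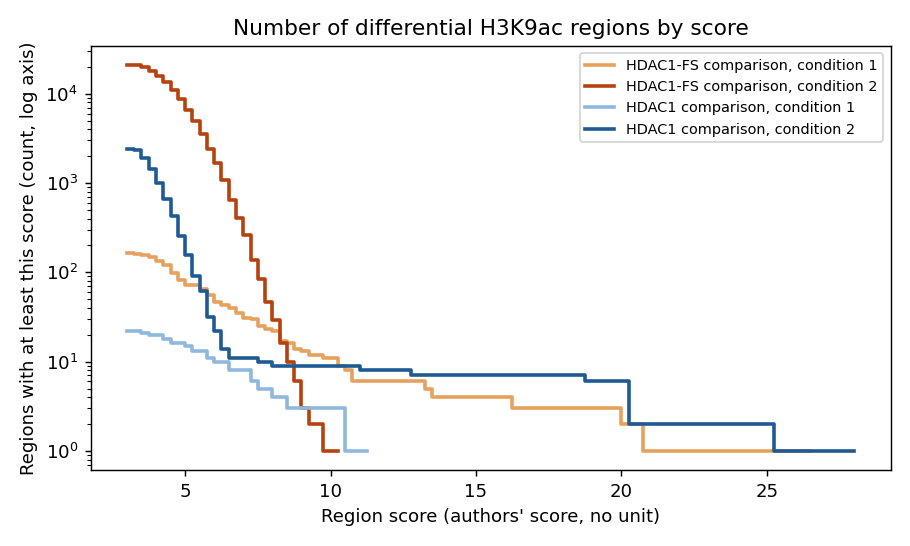
Number of listed regions (log axis) with at least the score on the horizontal axis, for both conditions of both comparisons, with no error shown because each list is a single result. In the HDAC1-FS comparison, condition 2 held 20841 regions against 164 at the authors' threshold, and 1 against 11 at a score of at least 10.

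The highest-scoring condition 2 region at a gene end lay at CYP7B1, an oxysterol hydroxylase gene (chromosome 8, 64798767 to 64798971, score 10.4). It was followed by MBOAT2, a lysophospholipid acyltransferase gene (chromosome 2, 9004088 to 9004426, score 9.51), and ATP6V0A1, which encodes a subunit of the vacuolar proton pump (chromosome 17, 42458920 to 42459346, score 9.10). GTF3C2, encoding a subunit of the RNA polymerase III factor TFIIIC, scored 8.89, FAM98A 8.81 and the autophagy gene ATG13 8.77. The other genes among the top 10 were PFDN2, encoding a prefoldin subunit (8.73), PPP2R5D, encoding a regulatory subunit of protein phosphatase 2A (8.66), ACADM, encoding medium-chain acyl-CoA dehydrogenase (8.58), and TMEM141 (8.57).

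Of 25 gene lists fixed before the data were examined, 16 had a share of members with condition 2 regions at or above the 97.5th percentile of 10000 random lists matched on gene length and crowding. Matching on expression was not possible, so the percentiles describe where the regions lay and are not p-values. Among chromatin regulators, 35 of 40 genes of the HDAC family and its complexes had a region, including MTA1 (score 7.14), REST (6.92), GATAD2A (6.55) and HDAC10 (6.28). All 25 acetyltransferase and bromodomain genes had one, led by KAT7 (7.24), TADA3 (7.21), KAT6A (7.09) and BRD1 (6.91). Matched random lists averaged 62.5% and 66.2% for these lists.

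Proliferation genes carried condition 2 regions as well, at 33 of 36 cell cycle genes and 38 of 43 DNA replication genes. They included the cyclin-dependent kinase genes CDK2 (6.24), CDK1 (5.98) and CDK4 (5.89), the replication genes GINS3 (7.1) and MCM7 (6.50), and the flap endonuclease gene FEN1 (6.47). CDK inhibitors and p53 targets had regions at 20 of 25 genes, among them XPC (6.30), MDM2 (6.24) and DDB2 (6.03). Apoptosis genes had regions at 29 of 35, led by BIRC5, which encodes survivin (6.85), and DIABLO (6.47). Genes of migration and adhesion had them at 32 of 40.

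Heat shock and unfolded protein response genes carried condition 2 regions at 33 of 36, with HSPA5, the endoplasmic reticulum chaperone BiP, at 7.33, SDF2L1 at 7.24 and ATF6 at 7.06. Immediate early genes carried them at 23 of 32, against a mean of 38.5% in matched random lists, with JUND at 6.75, IER3 at 6.64 and JUN at 6.60. Oxidative phosphorylation genes had regions at 52 of 59, led by the ATP synthase gene ATP5PB (7.86) and the complex I gene NDUFB8 (7.55). Glycolysis had 17 of 20, led by PKM (6.29), and cholesterol synthesis 21 of 25, led by the farnesyl diphosphate synthase gene FDPS (7.07). The top ribosomal protein genes were RPL8 (7.18) and RPL4 (7.14), the top proteasome gene PSMB5 (6.99) and the top splicing factor gene HNRNPK (6.65).

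HOX genes, which set position along the body axis, had condition 2 regions at 24 of 39, at the 98.3rd percentile, with HOXA13 (6.65) and HOXB13 (6.11) leading. Their place at or above the 97.5th percentile was lost when random lists were not matched. With a score of at least 5, the shares fell to 76.2% of splicing factor, 70.5% of ribosomal protein, 64% of acetyltransferase and bromodomain and 54.8% of proteasome genes. At that score, 12 of the 16 lists stayed at or above that percentile, and HOX, apoptosis, cholesterol synthesis and migration genes did not. Interferon and DNA sensing genes had them at 17 of 37, at the 17.1st percentile, led by ISG15 (6.69). Replication-dependent histone genes had them at 19 of 57 against 52.8% in matched random lists, and H2AC15 and H2BC15 shared a single region (5.25). Neuronal genes repressed by REST had 10 of 30, led by the tau gene MAPT (7.43), and kidney genes 8 of 25, led by SALL1 (5.57). Skeletal muscle genes had 6 of 28, led by ATP2A1 (6.27), and the 1 liver gene was TF (5.04) and the 1 epidermal gene DSC3 (4.98). The haematopoietic genes were CD4 (6.63), CD8A (5.86), CD68 (5.44) and CORO1A (5.07), and a region at a gene end can belong to a neighbouring gene. In all, 7 lists lay at or below the 2.5th percentile.

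**Figure D2:**
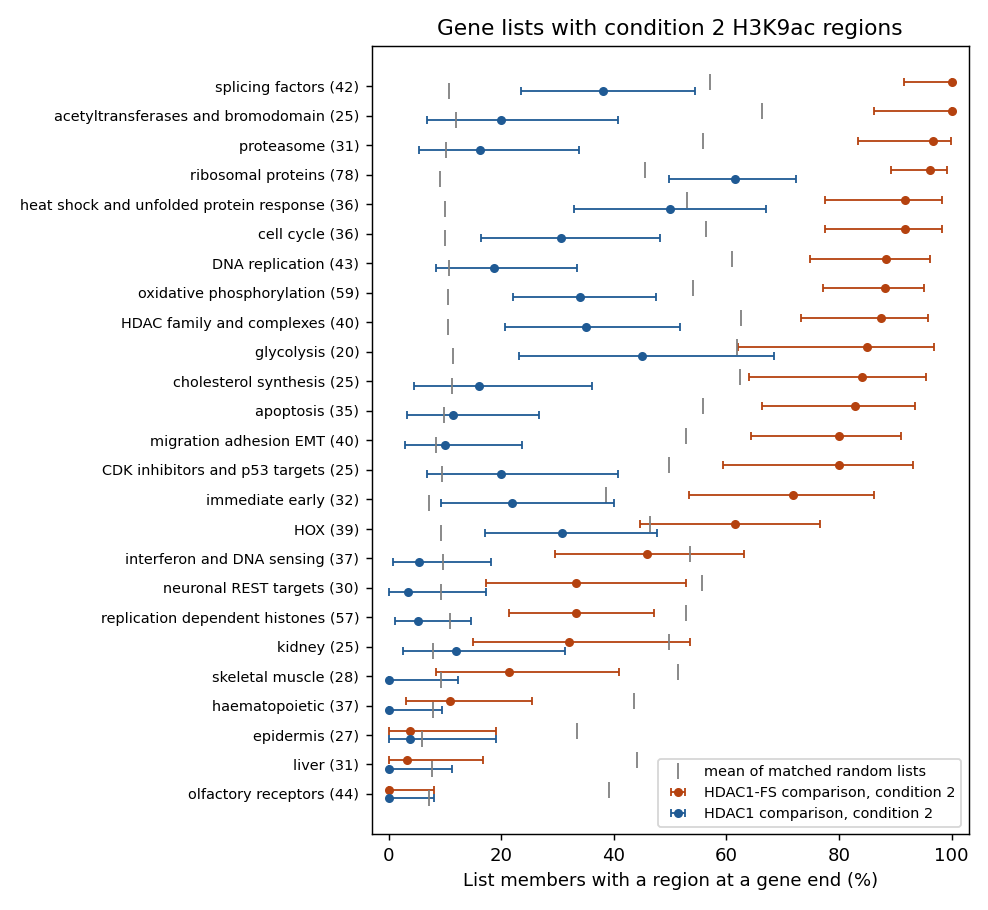
Percent of each gene list (members in brackets) with a condition 2 region at a gene end in the HDAC1-FS and HDAC1 comparisons, as points with exact binomial 95% intervals for counting error, and grey marks for the mean of 10000 matched random lists. Ribosomal protein genes had regions at 75 and 48 of 78 genes, and olfactory receptor genes at 0 of 44 in both comparisons.

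Condition 1 and condition 2 regions of the HDAC1-FS comparison differed in place. Of 20823 condition 2 regions on the main chromosomes, 14296 (68.7%) lay within 1 kb of a gene end, against 4.0% for the same regions placed at random. Only 31 of the 164 condition 1 regions did (18.9%, 95% interval 13.2 to 25.7%), while 110 (67.1%) lay inside genes away from the ends. The random placement took no account of where H3K9ac lies. The median distance from a region's midpoint to the nearest gene end was 1951 bp for condition 1 and 584 bp for condition 2. Between 1000 and 2500 bp from a gene end lay 48.8% of condition 1 regions (95% interval 40.9 to 56.7%) and 11.5% of condition 2 regions.

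**Figure D3:**
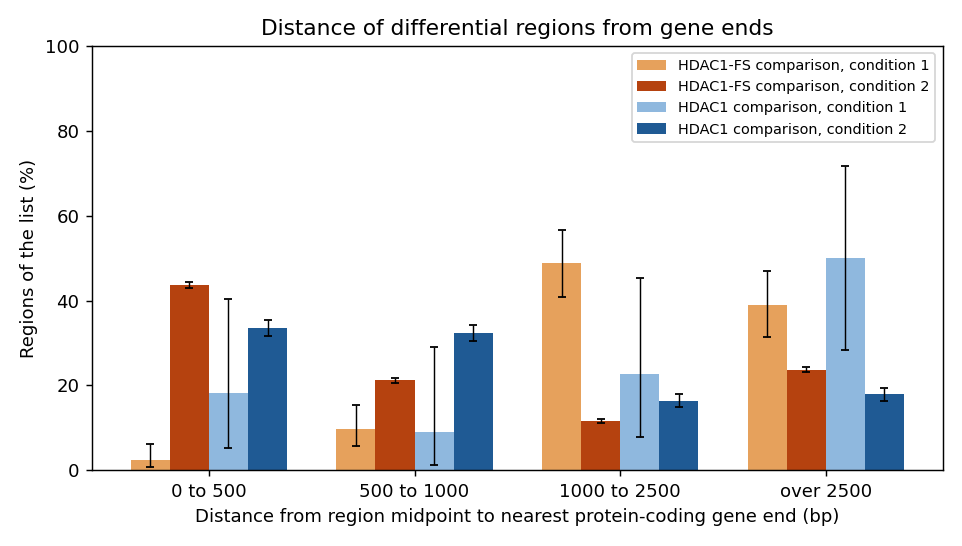
Percent of the regions of each list by distance in bp from the region's midpoint to the nearest protein-coding gene end, with bars for the 4 lists and exact binomial 95% intervals for counting error. In the HDAC1-FS comparison, 48.8% of condition 1 regions lay 1000 to 2500 bp away, and 43.6% of condition 2 regions lay within 500 bp.

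Beside TUBGCP5 (chromosome 15, 23038450 to 23038678), the condition 1 regions at gene ends with the highest scores lay at HOXD8 (chromosome 2, 176131890 to 176132157, 9.57) and GPX8, a glutathione peroxidase family gene (chromosome 5, 55160488 to 55160770, 9.20). They were followed by FASTKD1 (8.87), the coenzyme Q synthesis gene COQ3 (6.46), TMA16 (5.88), the mitochondrial carrier gene SLC25A32 (5.75), NBDY (5.71), RPAP2 (5.66) and the complex I gene NDUFB3 (5.45). HOXD8 and HOXA9 (4.08) made 2 of 39 HOX genes, NDUFB3 was 1 of 59 oxidative phosphorylation genes, and PSMD14 (3.69) was 1 of 31 proteasome genes. The other 22 lists had no member with a condition 1 region at a gene end. Several of the highest-scoring condition 1 regions lay away from gene ends and are named after their values were seen. They were a region between genes on chromosome 5 (181215610 to 181215895, 26.7) and regions inside the histone demethylase gene KDM5A (chromosome 12, 387254 to 387542, 19.8), the CDK inhibitor gene CDKN2A (chromosome 9, 21992359 to 21992752, 16.1) and the CDK inhibitor gene CDKN2C (chromosome 1, 50972492 to 50972777, 13.5).

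The HDAC1 comparison asked the same of cells with HDAC1 against empty vector. Condition 2 regions lay at the ends of 1871 of 19974 protein-coding genes (9.37%, 95% interval 8.97 to 9.78%), and condition 1 regions at 7. At the authors' threshold, those of condition 2 lay at 48 of 78 ribosomal protein genes (61.5%, 95% interval 49.8 to 72.3%), 18 of 36 heat shock and unfolded protein response genes and 9 of 20 glycolysis genes. With a score of at least 5, these shares were 3.85%, 8.33% and 5%. The highest scores of condition 2 lay inside HDAC1 itself and at pseudogenes, from 7.80 to 28.1. The highest score elsewhere in condition 2 was 7.32, at EPN2, which encodes the endocytic adaptor epsin 2.

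In all, 2427 regions were listed for condition 2 and 22 for condition 1, so condition 2 held 99.1% of the regions (95% interval 98.6 to 99.4%). The condition 2 regions covered 888 kb with a median width of 307 bp, and the condition 1 regions covered 5.89 kb with a median width of 236.5 bp. Median scores were 3.87 (quartiles 3.55 to 4.30) for condition 2 and 5.84 (4.52 to 7.35) for condition 1. Of 2423 condition 2 regions on the main chromosomes, 1718 (70.9%) lay at gene ends against 4.12% at random, and 7 of the 22 condition 1 regions did (31.8%, 95% interval 13.9 to 54.9%).

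HDAC1 lies on chromosome 1 from 32292083 to 32333626. In the HDAC1 comparison, 6 condition 2 regions lay inside the gene away from its ends. They were 32316595 to 32316884 (score 7.80), 32326849 to 32327150 (12.7), 32327456 to 32327772 (20.1), 32330498 to 32330965 (20), 32331474 to 32331901 (18.7) and 32332010 to 32332316 (20.2). At its start lay a region from 32292189 to 32292510 (5.75) and another from 32292627 to 32292953 (3.87). In the HDAC1-FS comparison, HDAC1 had a condition 2 region at its start (32292163 to 32293048, 6.06), and a region at its far end (32334383 to 32336199, 5.12) that lay over the neighbouring gene MARCKSL1. No region lay inside the gene, and condition 1 had no region at HDAC1 in either comparison. Exon positions were not used here.

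**Figure D4:**
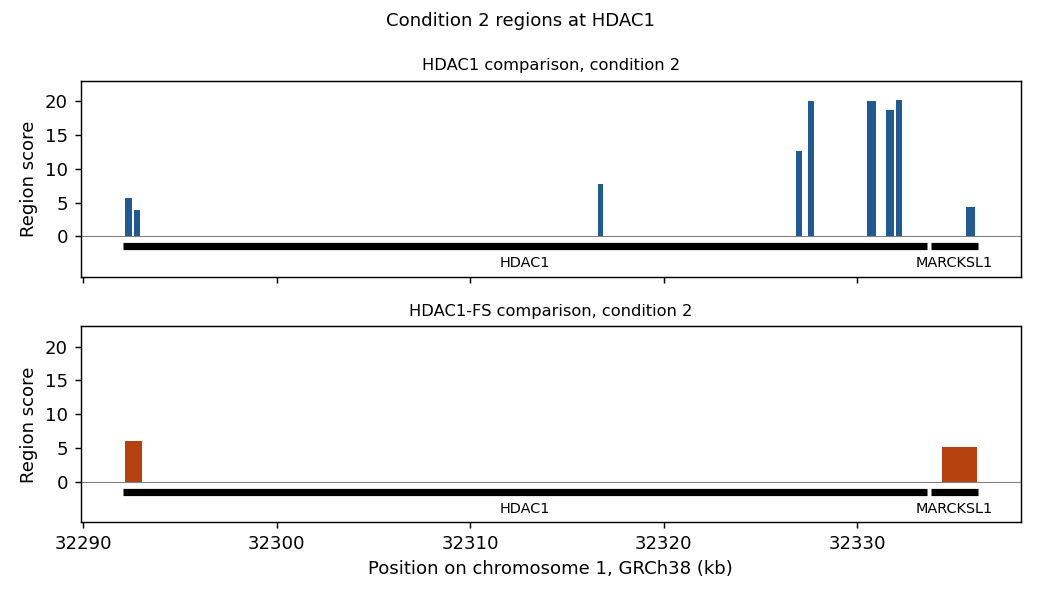
Score of each condition 2 region at HDAC1 and its neighbour MARCKSL1 by position in kb on chromosome 1 (GRCh38), with bars as wide as the regions and black lines for the genes, and no error shown because each region is a single call. In the HDAC1 comparison, 6 regions with scores from 7.80 to 20.2 lay inside HDAC1, and the HDAC1-FS comparison had none there.

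The genes with the highest-scoring condition 2 regions at their ends were EPN2 (chromosome 17, 19237481 to 19238551, 7.32), the protocadherin gene PCDH9 (chromosome 13, 67229774 to 67230226, 6.40) and RAI1 (chromosome 17, 17681425 to 17682326, 6.32). They were followed by COPS3, encoding a subunit of the COP9 signalosome (6.26), PEMT, encoding phosphatidylethanolamine methyltransferase (6.24), the lysosomal sulfatase gene GALNS (6.19), the nucleophosmin gene NPM1 (6.17), POLR2J3 (6.06), FKBP10 (5.94) and the Mediator subunit gene MED9 (5.90). EPN2, RAI1, COPS3, PEMT and MED9 lay on chromosome 17 between 15 and 25 Mb. That segment, chosen after these values were seen, held 123 condition 2 regions of the HDAC1 comparison (5.07% of its list) and 271 of the HDAC1-FS comparison (1.30%).

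For condition 2, 9 of the 25 gene lists lay at or above the 97.5th percentile of matched random lists. Ribosomal protein genes included RPL5 (5.26), RPL3 (5.17) and RPL32 (5.13), and the heat shock and unfolded protein response genes included the chaperone genes HSPH1 (5.35), HSP90AB1 (5.19) and HSP90B1 (5.11). Splicing factors had regions at 16 of 42, led by U2AF2 (5.84) and HNRNPU (5.20), and glycolysis genes were led by the aldolase gene ALDOA (5.01). Oxidative phosphorylation had 20 of 59, led by ATP5PB (5.07). HDAC family and complex genes had 14 of 40, namely HDAC1 itself (5.75) and among others GATAD2B (5.58), NCOR1 (5.22) and SAP30 (5.17). Cell cycle genes had 11 of 36, led by the cyclin D2 gene CCND2 (5.27), HOX genes 12 of 39, led by HOXA9 (5.63) and HOXA3 (5.48), and immediate early genes 7 of 32, led by KLF6 (4.75) and JUN (4.50). HOXA9 and HOXA3 lay close together on chromosome 7, and neighbouring members are not independent draws. With a score of at least 5, 4 of the 9 lists stayed there, and cell cycle, glycolysis, immediate early, oxidative phosphorylation and splicing genes did not. The 4 rested on few genes, at 10% of the HDAC family, 8.33% of heat shock, 5.13% of HOX and 3.85% of ribosomal protein genes. Those of the HDAC family included HDAC1, the transfected gene, and NCOR1, which lay in the chromosome 17 segment named above.

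DNA replication genes had condition 2 regions at 8 of 43, led by MCM7 (4.99), at the 94.6th percentile. CDK inhibitors and p53 targets had them at 5 of 25, including GADD45A (4.59) and CDKN1B (4.56), at the 95.1st percentile. Both lists passed the 97.5th percentile with windows of 500 bp and of 2.5 kb. The other lists lay below it, with acetyltransferases and bromodomain proteins at 5 of 25 (SUPT3H, 4.17), proteasome at 5 of 31 (PSMC4, 4.01), cholesterol synthesis at 4 of 25 (SREBF1, 5.1), apoptosis at 4 of 35 (BIRC5, 4.59) and migration at 4 of 40 (RHOA, 4.27). Kidney genes had 3 of 25 (SIX2, 4.25), histones 3 of 57 (H2AC20, 3.55), interferon genes 2 of 37 (ISG15, 4.71), REST targets 1 of 30 (MAPT, 5.1) and epidermal genes 1 of 27. Haematopoietic, liver, skeletal muscle and olfactory receptor genes had none, which with 37, 31, 28 and 44 members allows shares of up to 8.11%, 9.68%, 10.7% and 6.82% for counting error alone.

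The condition 1 regions at gene ends lay at USP40, a ubiquitin protease gene (chromosome 2, 233567100 to 233567313, 11.3), GPX8 (7.43), COQ3 (5.98), FRRS1 (5.70), the mitochondrial pyruvate carrier gene MPC2 (5.53), RPAP2 (5.16) and the cystine transporter gene SLC7A11 (4.43). No member of the 25 lists was among them. The regions at MPC2 and RPAP2 lay outside those genes, inside DCAF6 and GLMN, and the region at GPX8 also lay inside CDC20B.

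Both comparisons were then set side by side, to ask whether the same places were listed. Of the 1871 genes with a condition 2 region in the HDAC1 comparison, 1858 (99.3%) also had one in the HDAC1-FS comparison, where independent lists of these sizes would share 1012.5. That figure takes every gene as equally likely to carry a region, active or not, so it is no test. The shared genes with the highest scores in the HDAC1 comparison were EPN2 (7.32 there and 7.48 in the HDAC1-FS comparison), PCDH9 (6.40 and 6.03), RAI1 (6.32 and 6.57), COPS3 (6.26 and 7.38) and PEMT (6.24 and 6.26). For condition 1, GPX8 (7.43 and 9.20), COQ3 (5.98 and 6.46) and RPAP2 (5.16 and 5.66) had regions in both.

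Of the 2427 condition 2 regions of the HDAC1 comparison, 2227 overlapped a condition 2 region of the HDAC1-FS comparison (91.8%, 95% interval 90.6 to 92.8%), against a mean of 22.6 and at most 34 in 100 random placements. The placements were not limited to sites with H3K9ac, so they cannot show whether unrelated H3K9ac lists from these cells would overlap less. Requiring an overlap of 50% of both regions lowered the share to 36.7%. A region wholly inside a much wider partner fails that rule. Overlapping regions had median widths of 316 bp in the HDAC1 list and 736.5 bp in the HDAC1-FS list. Part of the fall may thus follow from width. Of the 22 condition 1 regions, 15 overlapped a condition 1 region of the HDAC1-FS comparison (68.2%, 95% interval 45.1 to 86.1%), among them the chromosome 5 region between genes (10.4) and the region inside CDKN2A (10.4). No region of either condition overlapped a region of the other condition in the other comparison. The HDAC1-FS list of condition 2 was 8.59 times as long by count and 10.8 times by covered length. These ratios moved with the score: with at least 5, the lists held 6645 regions (3548 kb) for HDAC1-FS and 155 (73.5 kb) for HDAC1, and with at least 10, 1 and 9 regions, where all 9 lay inside HDAC1 or at pseudogenes. The 2112 HDAC1-FS condition 2 regions that met an HDAC1 region had a median width of 736.5 bp, against 357 bp for the other 18729. Their median scores were 5.31 and 4.49. Under the 1 bp rule a wider region meets another more easily, so part of the width difference follows from the rule. Both comparisons used the same empty vector library, and part of the overlap may come from it. With no read counts, unchanged libraries could not be simulated against it.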

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

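The tests on HDAC1 pseudogenes were chosen after the result was seen. In the HDAC1 comparison, signal appeared at pseudogenes, outside the protein-coding genes the comparisons used. HDAC1P1 (chromosome 10, 94137730 to 94139002) carried a condition 2 region with a score of 10.9. HDAC1P2 (chromosome 1, 220625706 to 220627642) carried condition 2 regions with scores up to 25. LOC100132172 (chromosome 11, 114583262 to 114584549), a pseudogene whose parent gene is not named in the gene table used, carried the highest score of the list, 28.1. The HDAC1-FS comparison had 0 regions at these pseudogenes in either condition.

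The 6 condition 2 regions inside HDAC1 and the 4 at these pseudogenes made up the 10 highest scores of condition 2 in the HDAC1 comparison, and the highest score elsewhere was 7.32. The lower of the top scores at HDAC1P1 and HDAC1P2 was 10.9, and the 99th percentile of the list was 5.93. A change in H3K9ac at the HDAC1 gene alone would not give this if every read were placed at its own locus. How multiply aligned reads were handled is not given, and reads from HDAC1 could align to its pseudogenes. The pseudogenes therefore cannot decide against such a change. Reads from the transfected HDAC1 coding plasmid may account for the pattern, as 2 of 2 annotated HDAC1 pseudogenes at other loci carried condition 2 regions. On that hypothesis condition 2 of the HDAC1 comparison would hold the library with the HDAC1 plasmid, whereas the lists are named with the HDAC1 construct before the empty vector, which would make the empty vector condition 2 if that is the order of the conditions. It stays open why the HDAC1-FS comparison had no such region, because the sequence carried by its plasmid is not given in the sources used here.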

How the results depend on the processing

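Tests with a width of at least 400 bp, with regions at HDAC1 left out, with all HDAC1-FS regions as the partner set, and within genes with an HDAC1-FS region were chosen after the result was seen. Condition 2 kept the larger count in both comparisons under every alternative run other than a score of at least 10. With a score of at least 10 in the HDAC1-FS comparison, condition 1 had 11 regions and condition 2 had 1 (8.33% in condition 2). The cause was not tested. The HDAC1 comparison had 3 in condition 1 and 9 in condition 2 there (75% in condition 2), but all 9 lay inside HDAC1 or at pseudogenes, and no condition 2 region elsewhere scored above 7.32, so apart from them condition 1 held the larger count here too. With a score of at least 5, condition 2 held 6645 regions against 73 (98.9%) for HDAC1-FS and 155 (91.2%) for HDAC1, and covered lengths were 3548 kb (condition 2) and 20.4 kb (condition 1) for HDAC1-FS and 73.5 kb for HDAC1 condition 2, as the stricter score leaves fewer regions. Merging left 13714 HDAC1-FS condition 2 regions (98.9%). A width of at least 400 bp left 9646 and 13 (99.9%) for HDAC1-FS and 661 and 2 (99.7%) for HDAC1.

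The share of regions at gene ends moved with the window, as a wider window takes in more. With 500 bp and 2.5 kb it was 57.7% and 76.9% for HDAC1-FS condition 2, 5.49% and 62.2% for HDAC1-FS condition 1, and 49.6% and 83.0% for HDAC1 condition 2. With scores of at least 5 and 10 it was 77.5% and 100% (1 region) for HDAC1-FS condition 2, and 68.2% and 0% (9 regions) for HDAC1 condition 2. It was 9.09% at 10 for HDAC1-FS condition 1. The overlap of HDAC1 with HDAC1-FS in condition 2 was 36.7% with 50% of both regions, 73.5% with a score of at least 5 in both, 86.5% with that score in HDAC1 alone, and 99.3% for genes. For genes of condition 1 it was 42.9%. With a score of at least 5, the 155 HDAC1 condition 2 regions included the 10 inside HDAC1 or at pseudogenes. HDAC1-FS had 0 regions there, and none of the 10 lay at a gene end. These 10 therefore lowered the overlaps of 73.5% and 86.5% and the gene-end share of 68.2%.

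Gene lists at or above the 97.5th percentile fell from 9 to 4 for HDAC1 at a score of at least 5, and the cause was not tested. For HDAC1-FS the 16 lists became 12 there, losing HOX, apoptosis, cholesterol synthesis and migration. Unmatched random lists left 15 and 9, both other windows 16 and 11, and the background of HDAC1-FS genes 8 of the 9, without the immediate early genes. Shares of single lists moved beyond their interval in 40 of 50 cases at a score of at least 5, in 2 with 2.5 kb and in 1 with 500 bp. The alternative with a single start per gene was not run, since strand was not used here. No paired analysis was possible because each group had 1 library. Depth, which limits how many regions can be called, is unknown.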

Other observations

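The overlap between the comparisons was planned before the data were examined, and the test for condition 2 regions on both sides of a condition 1 region was chosen before its result was seen, though its draws with the direction kept and its count among regions with a neighbour were added later. The other tests given here, and the use of the overlap to weigh explanations, were chosen after the result was seen. Condition 2 of the HDAC1 comparison was also examined within the genes that had a condition 2 region in the HDAC1-FS comparison. Ribosomal protein genes still stood apart there, with 48 of 75 genes (64.0%, 95% interval 52.1 to 74.8%) against a mean of 19.4% in random lists. Those lists were matched on gene length and crowding, not on expression or HDAC1-FS score. HDAC1-FS condition 2 regions that met an HDAC1 region had a median score of 5.31, against 4.49 for the others. Ribosomal protein genes had an HDAC1-FS median of 5.49, so their share may follow from strong regions. The HDAC1 comparison had regions at 17 of 33 heat shock and unfolded protein response genes, 9 of 17 glycolysis genes and 12 of 24 HOX genes, against 18.3%, 18.1% and 19.8%. The highest-scoring HOX genes, HOXA9, HOXA3, HOXA5 and HOXA6, lay together on chromosome 7 between 25 and 30 Mb. That stretch had 37.5 HDAC1 condition 2 regions per 100 of HDAC1-FS, against 11.6 over all regions. Neighbouring members are not independent draws, so the HOX share may rest on few loci. Proteasome genes, of which 30 had an HDAC1-FS region, had 5 (16.7%), and acetyltransferase and bromodomain genes 5 of 25 (20%), close to their random means of 17.6% and 17.3%.

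Transfer RNA genes lay within 1 kb of 155 condition 2 regions of the HDAC1-FS comparison (0.744%, against 0.0395% at random) and of 10 in the HDAC1 comparison. They lay beside 3 of 164 and 2 of 22 condition 1 regions, including a region beside TRV-AAC1-5 on chromosome 6 that both condition 1 lists held, with scores of 10.0 (HDAC1-FS) and 8.47 (HDAC1). On chromosome 17 between 15 and 25 Mb, the HDAC1 comparison had 45.4 condition 2 regions per 100 of the HDAC1-FS comparison, against 11.6 over all regions. On chromosome 21 the ratio was 24.2 per 100. Of the 200 condition 2 regions of the HDAC1 comparison that met no HDAC1-FS region, 23.5% lay at gene ends, against 75% of the 2227 others.

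Nearly all regions belonged to condition 2 in both comparisons. An empty vector library of another strength or scaling, shared by both, is a candidate explanation. That library would have to be weaker if it was condition 1 and stronger if it was condition 2, and the order is not known. Under this explanation most places would be listed in both, and 91.8% of the HDAC1 condition 2 regions overlapped HDAC1-FS condition 2 regions. Like effects of both proteins would give the same. A shared library alone leaves open why the HDAC1-FS list was longer. A reversed order of conditions between the comparisons, with opposite effects, also stays open, because the 15 shared condition 1 regions would arise under either order. These explanations cannot be told apart without read counts, a replicate of the empty vector or a statement of the order.

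In the HDAC1-FS comparison, the median gap from a condition 1 region to the nearest condition 2 region was 911 bp, and 126 of 164 condition 1 regions (76.8%, 95% interval 69.6 to 83.1%) had a condition 2 region within 2 kb. Draws at the same distances from gene ends with condition 2 regions gave at most 68.3% with random direction and 71.3% with direction kept. The share lay above every draw of both kinds, whereas the position of active genes alone was taken to give a share within them. The 95% interval still reaches into the draws with direction kept, and each group had 1 library. The position of active genes alone therefore cannot be told apart from a closer link. Signal placed differently within the same loci, with condition 1 between condition 2 flanks, was predicted to put the share with condition 2 regions on both sides above all draws. Only 2 of 164 (1.22%, 95% interval 0.148 to 4.34%) had them. Among the 126 with a neighbour the share was 1.59% (95% interval 0.193 to 5.62%), against draws counted the same way of 6.54 to 20.6% with random direction and 6.90 to 24.3% with direction kept. The prediction was not met, which argues against that arrangement as far as these draws are a fair measure. A share below every draw was foreseen by neither written outcome, and its cause was not tested. Within 2 kb of an HDAC1 condition 2 region lay 5 of 22 HDAC1 condition 1 regions (22.7%, 95% interval 7.82 to 45.4%) and 37 of 164 HDAC1-FS ones (22.6%), and the draws decide nothing there, since they fall only at the 9.37% of genes with such a region. A shift of signal to 1 side was not tested, and no biological explanation was tested.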
